A study of Mus musculus with 2 samples.

How the data were processed

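H3K9ac ChIP-seq was measured in 14.5 day embryonic mouse heart, in 1 group of 2 biological replicates, each from tissue pooled from embryos of both sexes, per the labels. The authors deposited peak lists in narrowPeak form on mm10: a list for each replicate, a list from both replicates pooled, and a list of replicated peaks, per the file descriptions deposited with them. Column 7 of each deposited list was read as the authors' fold enrichment, a ratio over control, from the size of its values. Columns 8 and 9 were read as the authors' −log10 p and −log10 q values. The peak caller, the formula of the fold and the rule for replication are not given in the sources used here. The lists reach down to weak peaks: the lowest −log10 q in the replicated list was 0.402, so membership is not itself a test at a fixed q. Per the deposited descriptions, the replicate 1 list used a second control alignment that the replicate 2 list did not, so the replicate lists differ in their controls too. No control library was analysed here. The lists hold no read counts, so depth is unknown.

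Coordinates are mm10, used with the GRCm38 sequence and GENCODE annotation of the same build, and are printed counting from 1. Peaks on unplaced sequences were left out of chromosome-based counts. TSSs were the 54361 start sites of protein-coding transcripts of 21853 protein-coding genes. A gene was marked when a replicated peak overlapped a window of 1000 bp on either side of any of its TSSs, and its promoter fold was the highest fold of such peaks. Such a window can also take in a peak at the promoter of a neighbouring gene. Peaks outside promoters were placed in exons, introns or intergenic sequence by their summit. Domains were replicated peaks joined over gaps of up to 1000 bp. Distal peaks lay more than 3000 bp from any TSS and were counted within 50000 bp of any TSS of a gene. More sequence was therefore searched for genes with widely spread TSSs. Motif windows covered 150 bp on either side of the summit and of points 5000 bp away that lay clear of pooled peaks.

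Peak sets were compared by overlap of at least 1 bp, with 100 random placements on the same chromosome outside assembly gaps. Placement does not keep the clustering of peaks, so chance shares are approximate. The 23 gene lists and 15 motif consensus sequences, the tests and the rule for named genes were fixed before the data were examined. 1 list symbol was not in the annotation. Lists were tested by Fisher's exact test, two-sided, against other genes, with Benjamini-Hochberg adjustment over the lists, and motifs likewise over the motifs. Genes that neighbour each other can share peaks and are not independent replicates, so these p-values describe this tissue's lists and not variation between animals. Promoter strength was compared with 10000 random lists matched on the decile of promoter CpG observed over expected. A list outside the central 95% was called higher or lower. CpG content was taken within 500 bp of a gene's most upstream TSS only. The strongest peak of a gene can lie at another TSS, whose CpG content was not matched.

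The text names 10 cardiac genes chosen beforehand, up to 3 marked members of each list with the highest promoter fold together with its unmarked or marked members where few, or otherwise its first 3 unmarked members, the 10 genes with the highest promoter fold, the genes in the 10 longest domains, the 10 genes with most distal peaks and the genes nearest to the 10 strongest distal peaks. This rule took 137 genes.

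The tests were checked on simulated data. Lists simulated at 98 percent marked were called higher in 93% of 200 cases over 21853 genes, and unchanged lists were called in 2% of 350. Of 200 random lists drawn from the CpG deciles of the cell cycle list, 1% fell outside the CpG-matched central 95%. The range of the cell cycle list, 17 to 20 of 20 members, reaches the highest possible count. The rate therefore says little about lists of lower CpG content. With both replicate lists placed at random, 3.48% of peaks were shared on average, against 3.49% with the target list alone placed. Flank windows split at random gave 0 motif calls, and a planted MEF2 consensus was called with 0 other calls. These checks set flanks against flanks, so they could not show an effect of the GC difference between peaks and flanks.

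Alternatives were a reciprocal overlap of 50%, a −log10 q of at least 5, the top 20000 peaks, autosomes only, the pooled list, each replicate's list alone, other TSS windows, other gaps and reaches, matching or not matching on CpG content, a narrower motif window and GC-matched flanks in bins of 2%. The GC-matched comparison was first run on a single random draw. Because calls near the threshold changed from draw to draw, it was repeated over 100 draws after the data were seen, and the report gives those. Computation used Python 3.11.15 with numpy 2.4.6.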

Results

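H3K9ac, acetylation of lysine 9 on histone H3, is a chromatin mark found at active promoters and at active distal elements. It was mapped by chromatin immunoprecipitation and sequencing in heart tissue pooled from mouse embryos of mixed sex at 14.5 days. The series holds 1 group of 2 biological replicates and no second condition, so the comparisons below are between the replicates and between sets of genes or regions within the same tissue. The authors' peak lists held 64219 peaks for replicate 1 and 63653 for replicate 2. A list called on the pooled replicates held 76110 peaks, and the authors' replicated list kept 44754 of these. The lists give no read counts, so the depth of each library is unknown and no interval for read counts could be given. The fold enrichment printed for a peak is the authors' own value for that peak. It was used to describe, rank and filter peaks within a list, to set gene lists against random lists within the replicated list, and to correlate the ranks of overlapping peaks between the replicates.

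The strongest H3K9ac peaks were found in both replicates, and the peaks found in a single replicate were weak. Of the replicate 1 peaks on assembled chromosomes, 40500 of 64214 (63.1%) overlapped a replicate 2 peak by at least 1 bp. In the other direction 43048 of 63644 (67.6%) were shared. With the target list placed at random outside assembly gaps, 3.49% and 3.52% were shared on average, and none of 100 placements reached the observed share (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Placing the query list instead gave 3.06% and 3.21%, since placement breaks up the clustering of peaks: 31.1% of replicate 1 peaks had the next peak within 1000 bp, against 4.5% when placed. Shared peaks had a median fold enrichment of 4.51 in replicate 1 and 5.42 in replicate 2, and unshared peaks 2.98 and 3.49. No unshared peak reached a fold of 10, which 10049 shared peaks of replicate 1 and 12741 of replicate 2 did. Only 7.38% and 10.2% of unshared peaks lay at a promoter, against 45.1% and 46.0% of shared peaks.

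Fold enrichment ranked peaks in a similar order in both replicates. Over the 40505 replicate 1 peaks with an overlapping replicate 2 peak, Spearman's rho was 0.773 and Pearson's r of the log2 values was 0.846. Starting from replicate 2, rho was 0.747 and r was 0.807 over 43053 peaks. These correlations are across peaks, which are not independent replicates, and no p-value is given for them. Rho was 0.901 over peaks with a reciprocal overlap of 50%, a setting that also left fewer peaks, 28912.

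The replicated list kept 58.8% of the pooled peaks (95% Wilson interval 58.5 to 59.2, which covers counting error only). Promoter peaks were kept most often, 18007 of 20639 (87.2%), against 49.4% of exonic, 45.5% of intronic and 53.0% of intergenic peaks. Peaks kept had a median fold of 4.58 and peaks not kept 2.77. Every replicated peak was identical to a pooled peak, and 36042 (80.5%) were overlapped by a peak of each replicate. With only pooled peaks of −log10 q of at least 5, 96.9% were in the replicated list.

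Promoters of protein-coding genes carried the strongest H3K9ac. Of the 44750 replicated peaks on assembled chromosomes, 18007 (40.2%) lay within 1 kb of a transcription start site (TSS), against a mean of 3.88% for randomly placed peaks (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Their median fold was 13.3, against 3.74 for peaks elsewhere. Introns held 33.9% of the peaks, intergenic sequence 21.1% and exons 4.77%. A replicated peak marked the promoter of 14071 of 21853 protein-coding genes (64.4%). Using each replicate's own list, 14193 genes were marked in replicate 1 and 14206 in replicate 2, and 13893 were marked in both. The highest promoter fold belonged to the cytoskeletal actin gene Actb (chromosome 5, 142903115 to 142906754, mm10), at 66.7, with 50.8 in replicate 1 and 63.2 in replicate 2. Next in the replicated list came Gata4, a cardiac transcription factor gene, at 55.5. It did not hold this place in the replicates' own lists. There it had 29.7 in replicate 1 and 52.5 in replicate 2, against 43.6 and 60.2 for Rbm39. The following genes were Polr2m at 55.2, the splicing factor gene Srsf6 at 55.0, Rbm39 at 54.8, Rbpms at 54.5 and the stress-response factor gene Atf4 at 53.7. Gm10762 and Zc3h6 shared a peak of fold 52.8, and Hnrnpu had a fold of 52.0. The X chromosome held 4.89 peaks per Mb and had 47.7% of its genes marked, and chromosome 11, the densest, held 30.9 peaks per Mb.

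Cardiac gene lists fixed before the data were examined were almost fully marked. All 22 cardiac transcription factor genes had a replicated promoter peak, as did 21 of 22 sarcomere genes, 19 of 20 calcium handling and ion channel genes and 23 of 24 heart development signalling genes. Fisher's exact test against all other protein-coding genes, two-sided and adjusted over the 23 lists, gave adjusted p = 0.00028, 0.0022, 0.0052 and 0.0012. Matched on promoter CpG content, the signalling count lay inside the central 95% of random lists (18 to 23). Among the sarcomere genes the highest folds in the replicated list were at Myh7, encoding the beta myosin heavy chain, at 42.2, at the tropomyosin gene Tpm1 at 38.0, and at the atrial light chain gene Myl4 at 37.5. In the replicates' own lists Myh7 did not rank highest, with 25.3 in replicate 1 and 29.8 in replicate 2, against 30.7 and 36.2 for Tpm1 and 28.6 and 41.5 for Myl4. The peak that gave the fold of Myl4 in the replicated list (104548496 to 104550593) lay upstream of its most upstream TSS, at 104550663. The joined domain reached a TSS of Myl4. Whether this peak belongs to a neighbouring promoter was not examined. The unmarked sarcomere gene was Myom2, which had a peak of fold 2.13 in replicate 2 alone. Among the transcription factors, Gata4 at 55.5, Mef2a at 43.5 and Tbx20 at 41.3 ranked highest in the replicated list. Gata4 also ranked highest in replicate 2, at 52.5, but not in replicate 1, where its highest promoter fold, 29.7, lay at another of its TSSs and Nkx2-5 had 31.5. Hand2 reached 41.2, Nkx2-5 39.0 and Tbx5 17.7. Among the calcium and channel genes, Atp2a2, encoding the cardiac calcium pump of the sarcoplasmic reticulum, had a fold of 44.3, the potassium channel gene Kcnh2 38.1 and the ryanodine receptor gene Ryr2 31.5, and Sln lacked a peak. The pacemaker channel gene Hcn4 had a fold of 18.5. Of the signalling genes, Vegfa had 38.6, Notch2 33.9 and Fgfr2 30.6, and Shh was the unmarked member.

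Endothelial, fibroblast and valve, and smooth muscle lists were also marked more often than other genes. All 20 endothelial and endocardial genes were marked (exact test, adjusted p = 0.00061), with Notch1 at 19.5, Nfatc1 at 18.3 and Ets1 at 17.7. Of the fibroblast and valve genes 18 of 19 were marked (exact test, adjusted p = 0.0052), including the intermediate filament gene Vim at 30.6, Vcan at 22.7 and Fn1 at 17.6, and Lum was unmarked. Lum had a promoter peak of fold 2.73 in replicate 1 alone. Of the smooth muscle and pericyte genes 12 of 13 were marked (exact test, adjusted p = 0.047), with Cspg4 at 20.2, Smtn at 20.0 and Abcc9 at 16.0, and Mylk was unmarked. The smooth muscle call was lost at a −log10 q of at least 5 (76.9% marked), in the pooled list and with TSS windows of 500 bp. The natriuretic and trabecular list had 11 of 12 members marked and did not pass the exact test (adjusted p = 0.074), although its count exceeded the central 95% of random lists matched on promoter CpG content and it passed at a −log10 q of at least 5 and with the most upstream TSS only. Its members Xirp1, Erbb2 and Hspb7 had folds of 30.8, 28.3 and 27.0, while Nppa, the atrial natriuretic peptide gene, had 3.74, and Xirp2 was unmarked. The epicardial list, with 12 of 14 marked, did not pass the exact test (adjusted p = 0.16), but did without replicate 1 (92.9% marked). Tbx18 had 21.1, Tcf21 11.2 and Sema3d 10.99 in the replicated list, and Upk3b and Msln were unmarked. Upk3b had a promoter peak of fold 3.03 in replicate 2 alone.

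The oxidative metabolism, glycolysis, cell cycle and housekeeping lists were also fully marked. All 26 oxidative metabolism genes (exact test, adjusted p = 6.3e-05), all 16 glycolysis genes (adjusted p = 0.0021), all 20 cell cycle genes (adjusted p = 0.00061) and all 14 housekeeping genes (adjusted p = 0.0052) had a replicated promoter peak. Examples were Cox4i1 at 39.6, Sdhb at 36.9, Ndufs1 at 32.9, Pgam1 at 41.1, Eno1 at 39.4, the muscle enolase gene Eno3 at 36.3, Ccnd2 at 27.96, Mcm2 at 25.9, Ccnb1 at 22.6, Ubc at 49.2 and Ywhaz at 47.7. The cell cycle and housekeeping counts lay inside the central 95% of random lists matched on promoter CpG content. Those ranges, 17 to 20 and 10 to 14, reached the full list sizes of 20 and 14. Neither list could therefore have been called higher, so the matched comparison cannot decide whether CpG content accounts for their marking. Of the imprinted genes 13 of 14 were marked (exact test, adjusted p = 0.032), with Grb10 at 34.7, Igf2 at 25.9 and Igf2r at 22.6, and Ndn was unmarked. This call was lost in the pooled list and with the most upstream TSS only (85.7% marked).

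Genes of other lineages were marked less often than the rest. A promoter peak was found at 1 of 19 hepatocyte genes (exact test, adjusted p = 1.2e-06), 1 of 16 germ cell genes (adjusted p = 1.1e-05), 10 of 39 Hox genes (adjusted p = 1.1e-05), 5 of 19 skeletal muscle genes (adjusted p = 0.0021), 3 of 15 macrophage and leukocyte genes (adjusted p = 0.0013), 4 of 15 erythroid genes (adjusted p = 0.0063), 8 of 20 central neuron genes (adjusted p = 0.040) and 1 of 1092 olfactory receptor genes. The neural crest, glia and autonomic neuron list, with 5 of 12 marked, did not pass the exact test (adjusted p = 0.14). The skeletal muscle regulators Myod1, Myf5 and Myf6 were unmarked, whereas Mylpf had a fold of 31.3, Actn3 25.1 and Ckm 12.9. The peaks that gave the folds of Mylpf (127206432 to 127208695) and Actn3 (4878648 to 4879634) lay upstream of the genes' most upstream TSSs, at 127208890 and 4877909. The joined domain reached a TSS of both genes. Whether these peaks belong to a neighbouring promoter was not examined. In the erythroid list the transferrin receptor gene Tfrc had 29.1, Klf1 13.9 and Gypa 8.43, and the globin genes Hba-a1, Hba-a2 and Hba-x were unmarked. Hba-a1 and Hba-a2 are near-identical copies, and how shared reads were treated is not given in the sources used here. The macrophage genes Aif1, Spi1 and Cd68 had folds of 4.67, 3.59 and 3.43, and Ptprc, Csf1r and C1qa were unmarked. In the replicates' own lists Cd68 had a promoter peak in replicate 1 (2.29) but not in replicate 2. Hepatocyte genes Alb, Afp and Apoa1 were unmarked and Trf had 4.44. Dazl at 10.2 was the marked germ cell gene, and Ddx4, Sycp1 and Sycp3 were unmarked. Hoxb2 had 10.2, Hoxa1 7.64 and Hoxb4 7.37, and Hoxa3, Hoxa6 and Hoxa9 were unmarked. Of the neuronal genes Elavl4 had 13.6, Syt1 5.01 and Elavl3 4.82, and Neurod1, Neurog2 and Sox1 were unmarked. Neurog2 (3.36) and Sox1 (3.30) had a promoter peak in replicate 2 alone. Mpz had 25.7, Erbb3 8.69 and Ascl1 4.67, and Phox2a, Phox2b and Th were unmarked. Phox2a had a promoter peak of fold 2.86 in replicate 1 alone. Olfr94, at 3.01, was the marked olfactory receptor gene, and Olfr1, Olfr10 and Olfr1000 were unmarked. Matched on promoter CpG content, the erythroid, macrophage and skeletal muscle counts were inside the central 95% of random lists, and the neural crest count was below it, though not in the pooled list (6 marked, against 6 to 10). The Fisher call for central neuron genes was lost in the pooled list (55% marked) and without replicate 1 (50%), where the neural crest list passed as lower (33.3%).

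**Figure D1:**
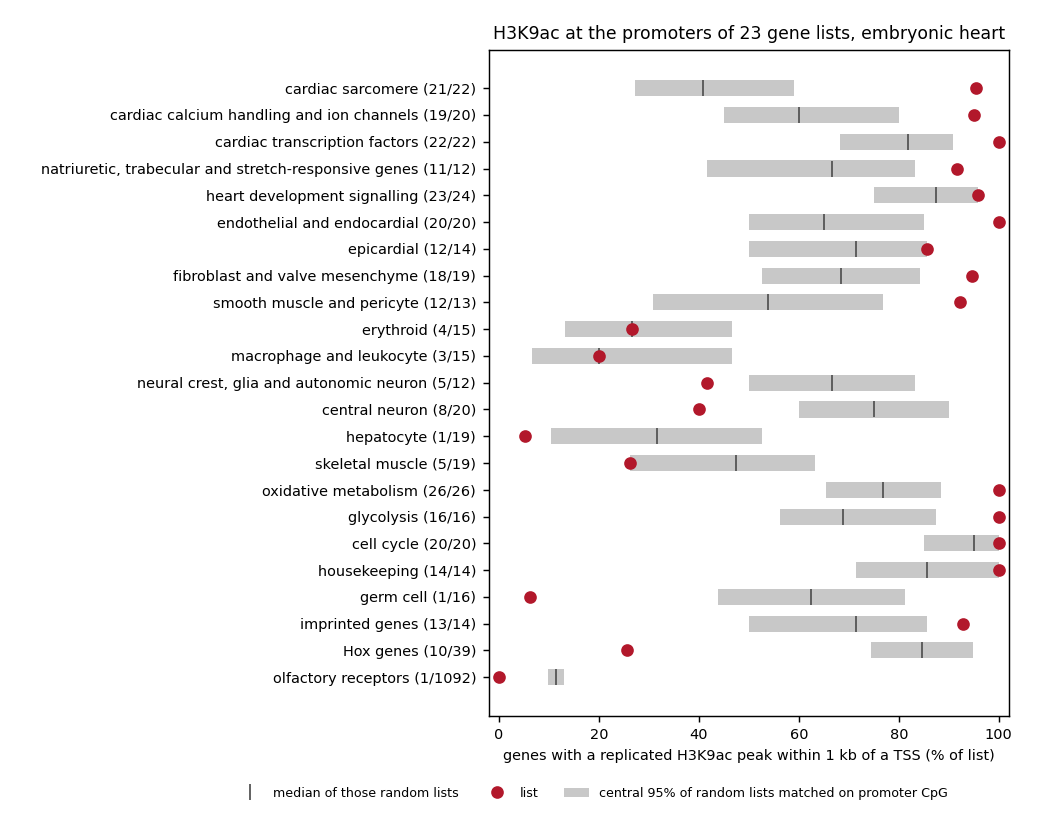
Percentage of each list's genes with a replicated H3K9ac peak within 1 kb of a TSS (red points, counts in parentheses), against the central 95% (gray bars) and median (ticks) of 10000 random lists matched on promoter CpG content. Sarcomere genes stand at 21 of 22 against a random range of 6 to 13, and Hox genes at 10 of 39 against 29 to 37.

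Among marked genes, promoter peak strength also differed between lists. The median promoter fold was 24.5 for sarcomere genes and 23.5 for cardiac transcription factors, against medians of 11.8 and 16.8 for random lists of marked genes matched on promoter CpG content. Glycolysis (32.6), housekeeping (32.0) and oxidative metabolism genes (21.9) were also above the central 95% of 10000 such lists. Central neuron (3.84), Hox (4.46), neural crest (4.67) and epicardial genes (7.21) were below it. The calcium handling list, at 18.7, lay inside the range, and above it without replicate 1 (20.7) and with the most upstream TSS only (18.8). The oxidative metabolism call was lost without replicate 1 and without the matching, and the housekeeping call with the most upstream TSS only. Without the matching, 9 lists were below the range rather than 4.

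Genes of several cardiac lists lay in long stretches of H3K9ac more often than other genes. Replicated peaks within 1 kb of each other were joined into 32640 domains, of which 12991 held a TSS, with a median length of 2053 bp. The longest 5% were at least 5380 bp. A TSS lay in such a domain for 17 of 21 sarcomere genes that had a domain (adjusted p = 3.7e-17), 13 of 22 cardiac transcription factors (adjusted p = 1.4e-10), 9 of 19 calcium and channel genes (adjusted p = 1.9e-06), 7 of 19 endothelial genes (adjusted p = 0.00024), 7 of 23 signalling genes (adjusted p = 0.00077), 4 of 8 natriuretic and trabecular genes (adjusted p = 0.0020), 5 of 16 glycolysis genes (adjusted p = 0.0043), 4 of 12 imprinted genes (adjusted p = 0.0091) and 4 of 16 fibroblast and valve genes (adjusted p = 0.025), by Fisher's exact test. About 5.5% of other genes did. The other 14 lists did not pass in this setting. Some of them were too small to pass or nearly so. The olfactory receptor list had 0 genes with a domain, and the macrophage, hepatocyte and germ cell lists had 1 each. The erythroid, neural crest and Hox lists had 3 each, and the central neuron and skeletal muscle lists 5 each. For these lists the test says little about long domains. The longest domain, 30826 bp (chromosome 14, 63227682 to 63258507), lay inside Gata4 (63198922 to 63271692). It held the internal TSSs at 63245248 and 63245271, and those at 63213607, 63271124 and 63271692 lay outside it. Hand2 lay in a domain of 26387 bp on chromosome 8 (57310066 to 57336452), Nkx2-5 in one of 22289 bp on chromosome 17 (26835807 to 26858095) and Gata6 in one of 21246 bp. The domain of Myh7 was 20905 bp and that of its neighbour Myh6, which encodes the alpha heavy chain and had a promoter fold of 13.9, was 20220 bp. Other domains among the 10 longest held Mical2 (23060 bp), the basement membrane gene Hspg2 (22558 bp), Igf2r (22110 bp), Unc5b (21077 bp) and Rbpms (20751 bp). The domain of Tnnt2, the cardiac troponin T gene, was 18656 bp, that of Tbx5 17105 bp and that of Actc1, the cardiac actin gene, 10892 bp. The fibroblast and valve call was lost without either replicate, this and the endothelial call at a −log10 q of at least 5 (20% and 21.1% of members), and both and the imprinted call with gaps up to 3000 bp. The glycolysis call was kept without replicate 1 (50% of members) and without replicate 2 (37.5%). Housekeeping genes passed in the pooled list (42.9%), without replicate 1 (35.7%), without replicate 2 (28.6%), with gaps up to 3000 bp and in the longest 10%. Oxidative metabolism genes passed with gaps of 500 bp or 3000 bp and in the longest 10%, and epicardial genes in the pooled list. In random lists matched on promoter fold, an alternative chosen after seeing the data, the glycolysis count lay inside the central 95% and the epicardial count above it.

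**Figure D2:**
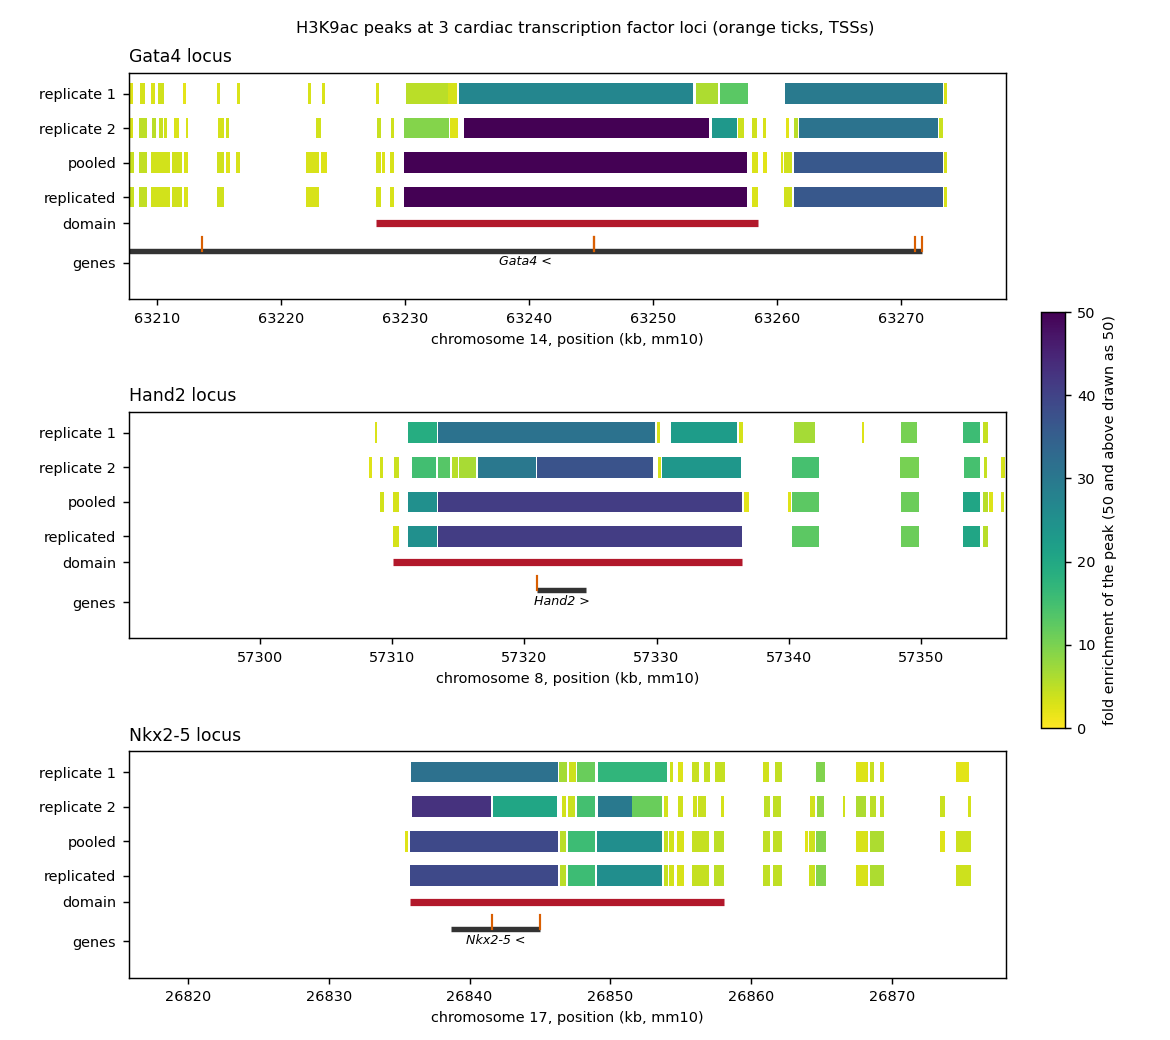
Peaks of the 4 deposited lists at Gata4, Hand2 and Nkx2-5 (horizontal axis, position in kb on mm10), colored by fold enrichment, with the joined domain (red), protein-coding genes (black, arrowheads give the strand) and their TSSs (orange). The domains are 30826, 26387 and 22289 bp long.

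Distal peaks were frequent around genes of 5 cardiac lists. There were 23124 replicated peaks more than 3 kb from any protein-coding TSS, with a median fold of 3.74, and 21.5% of genes had 3 or more of them within 50 kb. This held for 20 of 22 sarcomere genes (adjusted p = 7.4e-11), 18 of 22 cardiac transcription factors (adjusted p = 2.2e-08), 15 of 20 calcium and channel genes (adjusted p = 2.8e-06), 16 of 24 signalling genes (adjusted p = 1.2e-05) and 9 of 12 natriuretic and trabecular genes (adjusted p = 0.00044), by Fisher's exact test. Housekeeping (8 of 14, exact test, adjusted p = 0.013) and oxidative metabolism genes (11 of 26, adjusted p = 0.045) also passed, and olfactory receptor genes were lower, at 10 of 1092. The focal adhesion gene Tns1 had the most, 60, followed by Casz1 with 57, Mical2 with 52, Lrrfip1 with 44, and Gse1 and Rbm20 with 39 each. Dab2ip and Shb had 38 each, Tspan9 36 and Igf2r 33. This ranking of genes is not corrected for the length searched, which grows with the spread of a gene's TSSs. A peak inside a gene's own long domain also counted as distal if it lay over 3 kb from every TSS. The Gata4 peaks starting at 63227682, 63228790 and 63258004 were of this kind. Distal counts and long domains are therefore not independent measures, and peaks within domains were not left out. Nkx2-5 had 19, Gata4 16, Atp2a2 16, Myh6 13 and Nppa 4. The housekeeping and oxidative metabolism calls were lost within 100 kb and among genes with a marked promoter, where no list was lower. Both were also lost with at least 1 distal peak, and oxidative metabolism at a −log10 q of at least 5 (26.9% of members). The oxidative metabolism call was kept without replicate 1 (65.4%) and without replicate 2 (57.7%), against 42.3% in the replicated list. The natriuretic call was lost at that q (33.3%) and with at least 1 distal peak. Glycolysis genes passed in the pooled list (81.2%), without either replicate (68.8% in both cases) and with at least 1 distal peak. Endothelial genes passed in the pooled list (75%), within 100 kb (70%) and with at least 1 distal peak (85%), and Hox genes were lower without replicate 2 and at the stricter q. The replicate and pooled lists hold more peaks than the replicated list, so a higher percentage in these settings is not by itself stronger enrichment. Cell cycle genes went from 15% in the replicated list to 45% in the pooled list without passing.

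**Figure D3:**
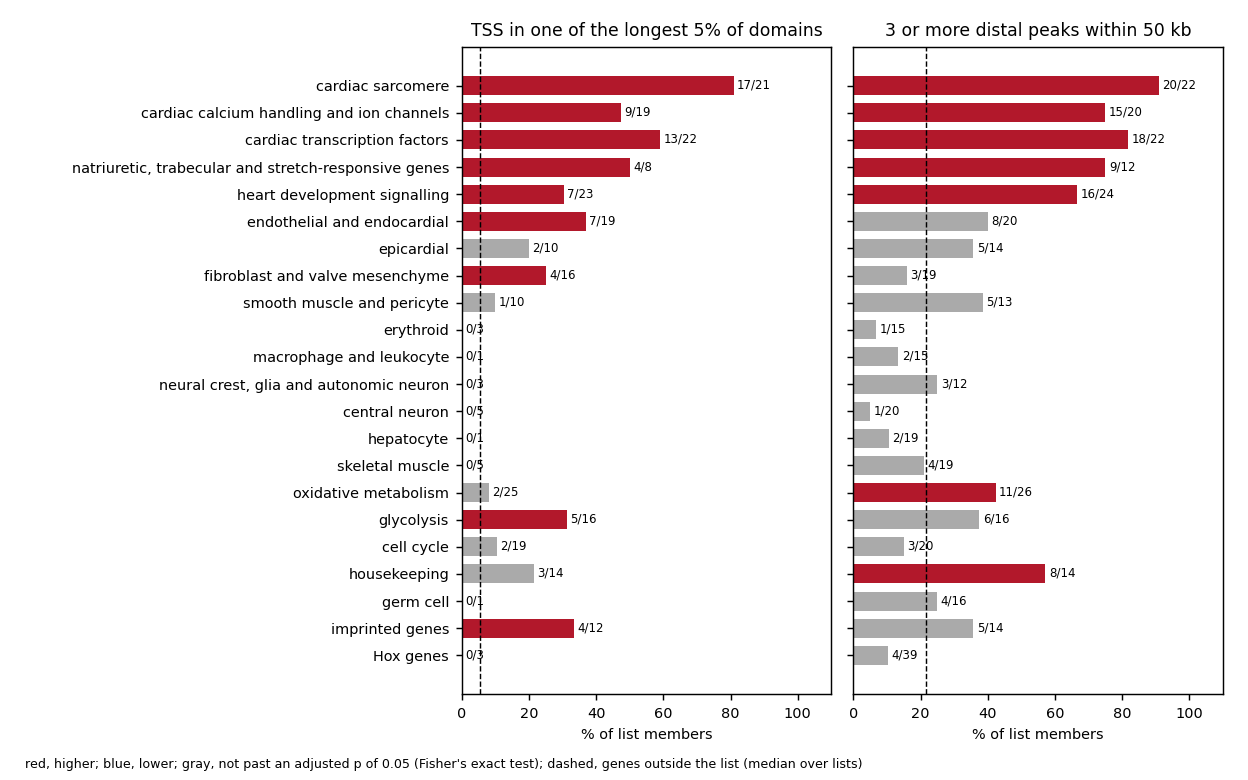
Percentage of list members with a TSS in one of the longest 5% of domains (left) and with 3 or more distal peaks within 50 kb (right), with counts beside the bars. Red bars passed Fisher's exact test at an adjusted p of 0.05 and lay above other genes (dashed line). Sarcomere genes lead both panels, with 17 of 21 and 20 of 22, and the olfactory receptor list, lower in the right-hand test, is not drawn.

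The strongest distal peaks often lay at the start of a noncoding gene. The strongest of all, with a fold of 63.3, was on chromosome 7 (73555918 to 73558622), in intergenic sequence 16.3 kb from the nearest protein-coding TSS, that of Chd2, and held a TSS of the noncoding transcript 1810026B05Rik within 1 kb. The next, at 44.6 on chromosome 11 (106500821 to 106502339), lay 13.4 kb from Ern1 at a small nucleolar RNA gene, Snord104. The following peaks were nearest to Hspa1b (42.6), A830005F24Rik (40.1), Tmem167b (38.7), Dapk3 (38.3), Mical3 (38.1), Ppm1h (37.5, at the microRNA gene Mirlet7i), Ndufs3 (36.8) and Epb41l4a (36.7). Of these 10 peaks, the one in an intron of Mical3 had no noncoding TSS within 1 kb. Noncoding here means any gene that the annotation does not type as protein-coding. At the Ndufs3 peak these were the pseudogene Gm17661 and Ptpmt1, typed as a processed transcript. Whether Ptpmt1 encodes a protein was not examined.

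Consensus motifs of transcription factors were counted within 150 bp of distal peak summits and in flanking windows 5 kb away. By Fisher's exact test adjusted over 15 motifs, the TEAD consensus was found in 8.84% of peak windows and 6.99% of flanks (odds ratio 1.29, adjusted p = 2.1e-15). GATA stood at 4.30% against 3.85% (odds ratio 1.12, exact test, adjusted p = 0.016), SOX at 3.24% against 2.90% (odds ratio 1.12, adjusted p = 0.036) and ETS at 0.143% against 0.063% (odds ratio 2.25, adjusted p = 0.0092). MEF2 was rarer in peaks, 3.30% against 4.58% (odds ratio 0.709, exact test, adjusted p = 2.2e-14), as were TBX (odds ratio 0.773, adjusted p = 0.0022) and NKX2 (odds ratio 0.895, adjusted p = 0.036). The other 8 motifs did not pass. Peak windows had a GC content of 52.0% and flanks 45.9%. With flanks matched on GC content, over 100 random draws, the direction turned for MEF2 (median odds ratio 1.82, range 1.63 to 2.02) and NKX2 (1.29, range 1.18 to 1.41), both past the threshold in all 100 draws. TEAD, GATA and SOX remained higher and TBX lower in all 100, and ETS passed in 1. The only E-box sequence counted, CATCTG, did not pass with the flanks as they lie. It was lower in peaks in all 100 draws (median odds ratio 0.905, range 0.883 to 0.927). With the flanks as they lie, the GATA call was lost at a −log10 q of at least 5 and within 75 bp of the summit, SOX and ETS within 75 bp, TBX without replicate 1, and NKX2 and ETS without replicate 2. CTCF, which had not passed, passed as higher without replicate 1 and as lower within 75 bp of the summit, where SRF also passed as lower. HNF1, which had not passed either, passed as lower without replicate 2, where 0.0027% of distal peaks held it.

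**Figure D4:**
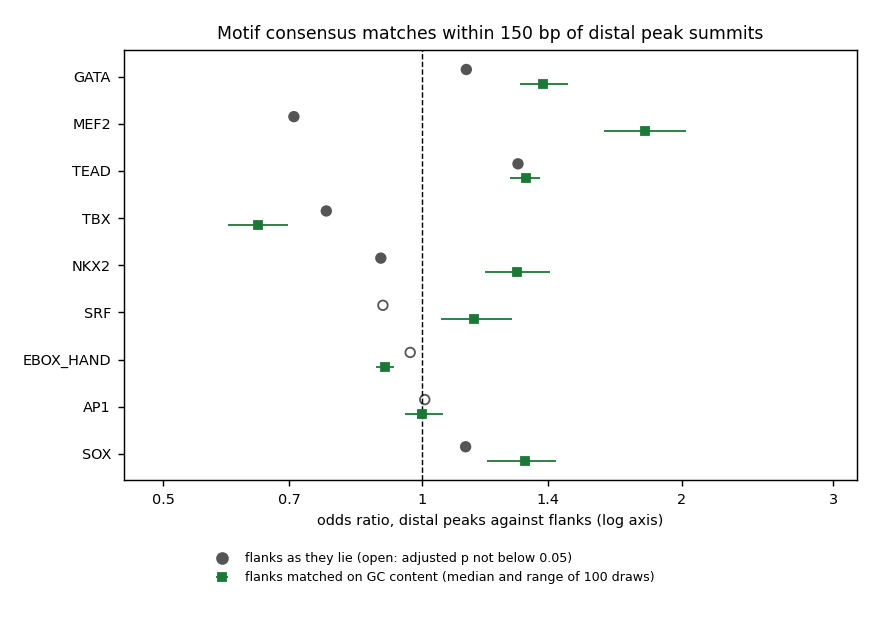
Odds ratio (log axis) of finding each motif consensus in distal peak windows against flanks, for the 9 motifs with at least 100 peak windows holding a match. Gray circles use flanks as they lie, and green squares with bars give the median and range of 100 draws of GC-matched windows. MEF2 moves from 0.709 to 1.82 and NKX2 from 0.895 to 1.29.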

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

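Matching long domains on promoter fold, counting each domain once, matching distal peaks on the length searched and repeating the GC-matched draws were chosen after seeing the data. No paired analysis was possible because the series holds a single group. Leaving out a replicate cannot be done for the overlap, the rank correlation or the replicated share, which need both lists. For other results it means the remaining replicate's own list. The counts of lists called higher, and of lists called lower in promoter marking, stayed within 1.5 times of the main count under all alternatives run. For single lists and motifs, 41 calls were lost and 39 gained in the same direction over all alternatives, and 704 values kept both. Unknown depth limits all statements about unmarked genes.

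The rank correlation rose from 0.773 to 0.901 with a reciprocal overlap of 50%, 0.8598 at a −log10 q of at least 5 and 0.851 in the top 20000 peaks, and the replicated share rose from 58.8% to 96.9% at that q. Lists with weak promoter peaks numbered 9 rather than 4 without CpG matching. Lists with few distal peaks numbered 2 at a −log10 q of at least 5, between 1 and 2 without replicate 1 or without replicate 2, and 0 among genes with a marked promoter, against 1. Within 75 bp of the summit 1 motif was higher and 5 lower, against 4 and 3. The cause of these shifts was not tested.

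Directions turned in 53 cases, of which 48 passed the threshold in neither setting, and the other 5 were motifs. For the median promoter fold these were natriuretic genes (16.8), skeletal muscle (12.9) and cell cycle (18.8) without CpG matching, signalling at the stricter q (18.7), skeletal muscle in the pooled list (5.66) and with TSS windows of 500 bp (6.83) or 2500 bp (9.88). Leaving out a replicate turned signalling (12.3 to 20.5), smooth muscle (7.82 to 8.66), skeletal muscle (7.66 to 17.1) and imprinted genes (11.4 to 17.5) (ranges over both cases). For long domains they were epicardial genes at the stricter q (0%) and Hox genes with gaps up to 3000 bp (33.3%).

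For distal peaks, at the stricter q they were fibroblast, skeletal muscle (15.8% each), macrophage (13.3%), cell cycle (15%) and germ cell genes (12.5%). In the pooled list they were macrophage (40%), neural crest (33.3%), cell cycle (45%) and Hox genes (41.0%). Within 100 kb they were macrophage (53.3%), cell cycle (50%) and Hox genes (46.2%). With at least 1 distal peak they were fibroblast (57.9%), smooth muscle (46.2%), macrophage (60%), skeletal muscle (52.6%), cell cycle (60%) and Hox genes (66.7%). Among marked genes they were macrophage (33.3%), skeletal muscle (40%) and germ cell genes (0%). Leaving out a replicate turned neural crest (33.3% to 41.7%), hepatocyte (26.3% to 42.1%), skeletal muscle (26.3% to 36.8%), cell cycle (35% to 40%) and Hox genes (12.8% to 30.8%) (ranges over both cases).

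For motifs, in a single GC-matched draw MEF2 (3.87% of peaks), NKX2 (3.59%), SRF (1.38%) and CTCF (0.278%) turned. That draw called SRF higher, which only 4 of 100 draws did (median odds ratio 1.15), so no SRF result is claimed. The E-box turned in the pooled list (23.9%) and without a replicate (23.5% and 23.6%), AP1 (4.92%) and NFI (0.044%) at the stricter q, HNF4 (0.401%, against 0.414% without replicate 1) and NFI (0.040%, against 0.023%) without replicate 2, and ETS (0.026%) and CTCF (0.052%) within 75 bp, where CTCF and SRF passed as lower. The cause was not tested.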

Other observations

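Gene families defined by symbol, chosen after the data were seen, extended the picture. All 37 genes with Nduf symbols, most of them for respiratory complex I subunits, had a replicated promoter peak, as did 39 of 40 with Psma to Psmd symbols, most of them for proteasome subunits, and 89 of 98 with ribosomal protein symbols, by Fisher's exact test adjusted over 22 families (adjusted p = 3.2e-07, 2.6e-06 and 7.9e-09). The symbol match also took genes of other function, such as Ndufa4 and Psmc3ip. Matched on promoter CpG, the ribosomal count lay inside the central 95% of random lists (81 to 90), and the other counts lay above theirs (30 to 36 and 32 to 38). Zinc finger genes named Zfp were marked in 338 of 394 cases, above the 289 to 315 of the central 95% of random lists matched on promoter CpG. Of 9 Pax genes, encoding developmental transcription factors, Pax6 was the only member marked in the replicated list (exact test, adjusted p = 0.0035), with a fold of 3.12. Pax1 (3.85 and 4.18) and Pax9 (2.59 and 3.64) had a promoter peak in each replicate's own list. Keratin genes were marked in 7 of 53 cases, among them Krt8, Krt18 and Krt19. Of 52 clustered protocadherin genes, the 18 marked were all from the gamma cluster. Of 9 muscle myosin heavy chain genes, Myh6, Myh7 and Myh7b were marked, and all 6 Iroquois factor genes were marked, though neither family passed the test. Outside protein-coding promoters, 2085 replicated peaks held a TSS of a noncoding gene within 1 kb.

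No biological explanation was tested for the patterns below, since the series holds a single group. The CpG test of Hox and neuronal promoters was chosen after its result was seen.

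Sarcomere and cardiac transcription factor genes often lay in the longest 5% of domains, which strong promoters, promoter CpG content or neighbours sharing a domain could give. Against random lists matched on promoter fold, 17 sarcomere and 13 transcription factor genes compared with upper limits of 5 each, an excess of at least 8 members, and matched on CpG content the excess was at least 9. No members of the same list shared a domain: the 21 sarcomere genes lay in 21 domains and the 22 transcription factor genes in 22. Sharing therefore cannot give the pattern. Counting each domain once could not change either count (larger adjusted p = 7.6e-11, Fisher's exact test) and was no separate test. None of these accounts for the pattern alone. Matched on promoter fold, imprinted (4 of 12), endothelial (7 of 19) and fibroblast genes (4 of 16) were among the other lists above the central 95%. Each gene was given the longest domain that held any of its TSSs, and the random lists were not matched on the number of TSSs. That difference, read depth and peak merging by the authors' caller stay open.

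The MEF2 consensus was rarer in distal peaks than in flanks. Base composition is a candidate explanation: 50 shuffled versions of the consensus had a median odds ratio of 0.366, between 0.261 and 0.553, and all 50 lay below that of MEF2, 0.709. With flanks matched on GC content, MEF2 was higher in peaks in all 100 draws (median odds ratio 1.82, range 1.63 to 2.02). Shuffling keeps base content but not neighbouring-base preferences, which stay open.

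Hox and central neuron promoters were seldom marked, at 10 of 39 and 8 of 20, where CpG-matched random lists had medians of 33 and 15. Low CpG content at the most upstream TSS, the only one matched, was argued against: both counts fell below the lower limit of those lists, by at least 4 members. In the pooled list 13 of 39 Hox and 11 of 20 neuronal genes were marked, at least 2 members below that limit, which argues against the replication filter as the whole cause. Fisher's exact test no longer called the neuronal list in the pooled peaks (55% marked), so a part for the filter there stays open. Hox genes lie in clusters and are not independent, so the random lists may understate chance variation for them.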
